A study of Mus musculus and Bos taurus with 26 samples.

How the data were processed

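PolyA RNA of 26 embryo libraries was analysed, 22 from mouse in 11 groups and 4 from cattle in 2 groups, with 2 libraries in each of the 13 groups. Groups, times and doses came from the labels. Per the labels' protocols, total RNA was taken from whole embryos with a Picopure kit, mRNA was drawn out on oligo(dT) beads, and libraries were made by fragmentation, reverse transcription, adaptor ligation and PCR. No strand-marking step is described in the labels, so reads of a gene and of an overlapping or antisense gene may not be told apart. The labels do not say that the replicates of a group came from separate cultures, and p-values therefore measure only the spread between these libraries, which may be technical.

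The values were the FPKM (fragments per kilobase of transcript and library size) that the authors deposited per gene and library, in a table for each species. Per the submitters' processing notes, the tools named were Trimmomatic, HISAT2, featureCounts, Cufflinks and DESeq2, with the builds GRCm38 for mouse and ARS-UCD1.2 for cattle; tool versions and the role of each are not given in the sources used here. DESeq2 was used by the authors, per those notes, and was not used here, because FPKM are not counts. FPKM divide by gene length and by each library's total, so a change in a few abundant genes shifts every other value, and total RNA per embryo is not seen. There were 27988 genes in the mouse values and 21577 in the bovine values, and 0 per-sample columns were left without a sample.

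Absolute sequencing depth is unknown from FPKM. The relative depth of libraries was estimated from the most frequent ratio between the values of low genes in pairs of libraries. In mouse, 98.7% of 231 pairs fitted a single depth per library within 0.06 on the log2 scale, although a median of only 10.3% of low genes lay at that ratio, so the estimates are rough. In cattle, 100% of 6 pairs did so. On simulated values for 8 libraries and 15000 genes, the largest error of the estimate was 0.019 on the log2 scale. No counting intervals were computed.

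Genes with an FPKM of at least 1 in at least 2 libraries were tested, 17336 in mouse and 12590 in cattle. Values were taken as log2(FPKM + 1), a scale that understates the change of low genes. A gene that is silent in controls passes this filter mainly by being high in some other group, so lists of such genes lean toward higher members. limma 3.58.1 in R 4.3.3 was fitted to all 22 mouse libraries with a coefficient per group (11 residual degrees of freedom) and separately to the 4 bovine libraries (2 residual degrees of freedom), with an empirical Bayes variance trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, and a call meant an adjusted p under 0.05. There were 10 comparisons of 2 groups and 3 differences between comparisons. Values are given as mean ± SD (n = 2 libraries in every group) and fold changes as log2 ± SE. An exact 0 can be a failed estimate in such tables, so a gene at 0 in both libraries of a group compared is said to be listed at 0 with its libraries given singly, and a gene at 0 in 1 of them is marked so. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for depth and plots.

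Gene coordinates are those of GENCODE release M21 on GRCm38, matched by symbol; 27557 of the 27988 mouse symbols and 17051 of the 17336 tested had a match. Bovine coordinates were not used here. Members of multigene families (Zscan4, Usp17l, Trim43, Pramel, Obox, Tdpoz, Duxf3, histones, Hba and the Rps27 pair) can share reads with near-identical copies, and their values are uncertain for that reason.

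The groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Named genes in each main comparison were the up to 8 that rose and 8 that fell with the largest log2 fold change among calls, with groups that did not overlap, a mean of at least 5 FPKM in the higher group and a symbol that was not a clone or predicted model; the first 3 each way were taken in other comparisons. To these came up to 4 called members of each list, by size of change, and Hdac1, Hdac2 and Kdm5b everywhere. For the differences between comparisons, overlap and level were checked only in the groups of the first comparison. Lists covered cytosolic ribosomal proteins, ribosome biogenesis, translation initiation, pre-mRNA splicing, proteasome, cell cycle, maternal oocyte factors, 2-cell burst genes, Obox and ZGA activators, eutherian embryonic genome activation genes (bovine only), pluripotency and lineage factors, imprinted genes, histone deacetylases, HDAC1/2 corepressor complexes, histone acetyltransferases and readers, H3K4 methylation enzymes, DNA methylation machinery, HDAC inhibitor-induced genes, neuronal and secretory genes, p53 targets, integrated stress response, heat shock genes, mitochondrially encoded mRNAs, and markers of cumulus and granulosa cells, blood and sperm. A list with at least 5 tested members was tested against all other genes with limma's camera at its preset correlation of 0.01, and again with an estimated correlation; p-values were adjusted over the lists of a comparison, fixed lists and lists chosen on the data separately. Stage lists were chosen on water-injected late embryos against early Hdac1 WT embryos (log2 fold change of at least 2 either way) and tested only where neither group was used.

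On simulated values with known changes, the tests of Hdac1 mutant against WT late embryos called 8% of 50 genes changed by 0.5 on the log2 scale, 62% at 1 and 100% at 2 and at 3, with 8 false calls among 17086 unchanged genes. For the change of that effect from early to late, the shares were 4%, 30%, 86% and 100%, with 4 false calls. For the bovine comparison they were 4%, 80%, 100% and 100%, with 9 false calls among 12340. The changed genes were drawn only from those well expressed in the control group, so these shares do not hold for low genes. Far fewer genes changed in the simulations than were called in the late mutant and FK228 comparisons.

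Alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, median-ratio scaling, quantile normalization, no variance trend, the replicate number as a block, only the groups compared, each library left out in turn, an estimated set correlation and a stage-list threshold of 4. A correction for gene length was chosen after seeing the data, and so were list tests without the injected genes and counts with no filter for gene families and blood markers. With a library left out, the remaining library of its group is assumed to vary like those of the other groups.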

Results

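RNA was profiled in 26 libraries of preimplantation embryos, 22 from mouse and 4 from cattle. Mouse zygotes were injected with water or with mRNA for wild-type (WT) or mutant Hdac1 or Hdac2, histone deacetylases shared by several corepressor complexes; the labels do not give the mutations. Embryos were taken as late 2-cell embryos 36 h after fertilization, and those with Hdac1 WT or mutant mRNA also as early 2-cell embryos at 24 h. A further 2 groups received mutant Hdac1 mRNA as zygotes and then, in both blastomeres of the early 2-cell embryo, water or mRNA for Kdm5b, a demethylase of histone H3 lysine 4. Other mouse embryos were cultured from the zygote stage in 50 nM FK228 (romidepsin, an inhibitor of class I histone deacetylases) or its solvent DMSO. Bovine 8/16-cell embryos were cultured in 50 nM FK228 or DMSO and taken at 72 h. The title of the series puts the question of whether HDAC1/2 is needed for zygotic genome activation (ZGA), the onset of transcription from the embryo's own genome.

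Between 10704 and 14554 genes reached 1 FPKM in a mouse library and between 11598 and 12141 in a bovine library. The replicates of a group correlated across genes with r from 0.933 (the Hdac1 mutant late libraries) to 0.987 in mouse and from 0.976 to 0.98 in cattle. Estimated depth relative to the median library ran from 0.669 (Hdac1 mutant early replicate 2) to 1.31 (Kdm5b replicate 1) in mouse and from 0.915 to 1.063 in cattle. The 10 most abundant genes held 7.1% to 15.9% of the summed FPKM in mouse and 4.4% to 13.7% in cattle. The highest share in cattle was that of FK228 replicate 2, where LOC112442485 stood at 23828 FPKM and was listed at 0 in the other bovine libraries; this gene was chosen after its values were seen.

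The injected genes stood out in the libraries labelled with them. Hdac1 (GRCm38 chromosome 4, 129516104 to 129542713, minus strand, protein coding) was at 2834 ± 179 FPKM in Hdac1 WT and 4782 ± 240 in Hdac1 mutant late embryos, against 90.8 ± 2.05 in water-injected embryos. At the early stage it was at 5886 ± 1933 in WT and 3479 ± 746 in mutant embryos. Hdac2 (chromosome 10, 36974544 to 37001889, plus strand, protein coding) was at 1618 ± 222 in Hdac2 WT and 2367 ± 107 in Hdac2 mutant embryos, against 22.8 ± 5.10 in water-injected embryos. Kdm5b (chromosome 1, 134560171 to 134635285, plus strand, protein coding) was at 616 ± 31.5 after Kdm5b mRNA and 67.6 ± 8.96 after the second injection of water. Hdac1 was at 842 ± 24.6 and 861 ± 79.0 in these same groups. The values cannot tell transcripts of the embryo from injected mRNA.

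**Figure D1:**
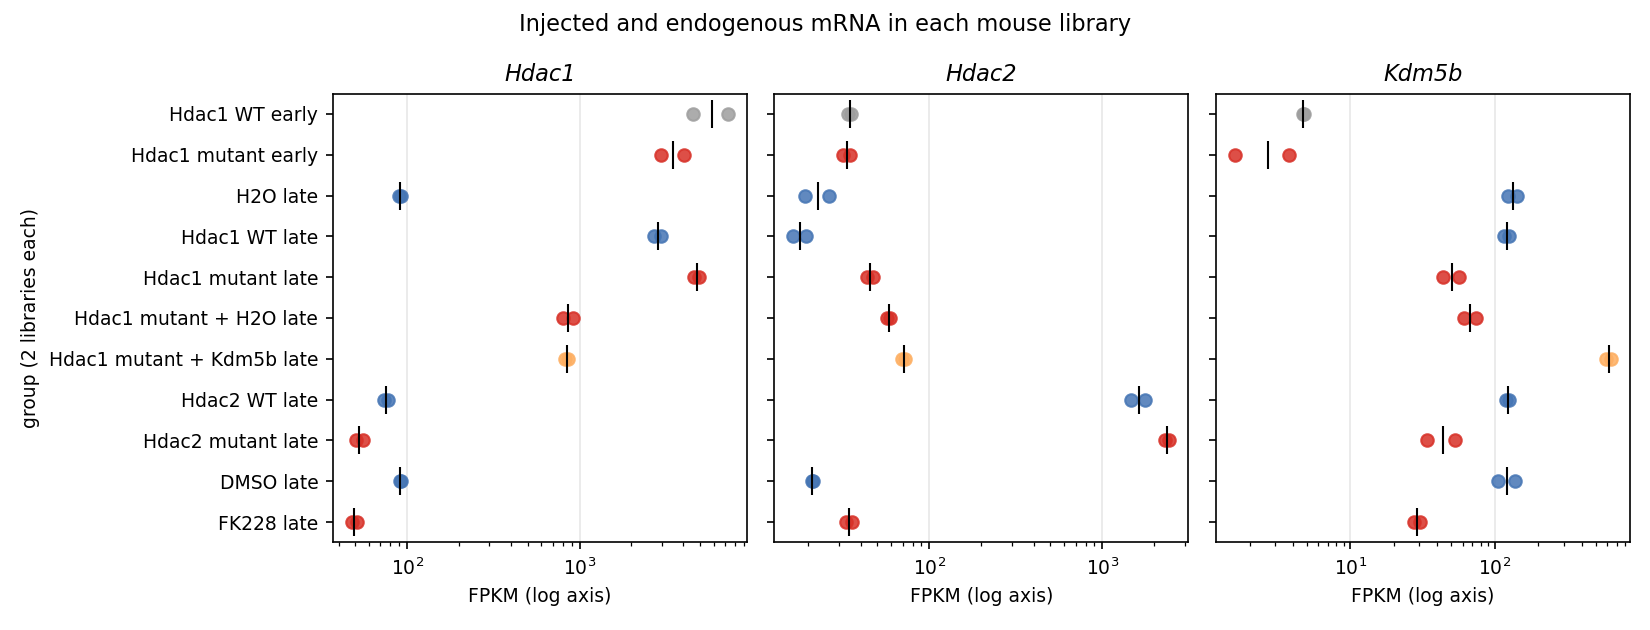
FPKM (log scale) of Hdac1, Hdac2 and Kdm5b in each of the 22 mouse libraries, with points for libraries and bars for group means. Hdac1 was highest in the singly injected Hdac1 groups, and Kdm5b was lower in Hdac1 mutant, Hdac2 mutant and FK228 late embryos than in their controls.

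The change from the early to the late 2-cell stage was read in Hdac1 WT embryos. Oocyte transcripts were lower at the late stage: Bcl2l10 fell from 3611 ± 140 to 72.0 ± 0.397 FPKM and Rfpl4 from 2240 ± 57.6 to 41.6 ± 3.95. Btbd18 rose from 1.97 ± 1.17 to 262 ± 30.5, Selenos, a selenoprotein of the endoplasmic reticulum, rose from 1.39 ± 0.356 to 158 ± 7.64, and Kdm5b itself rose by 4.41 ± 0.25 on the log2 scale (adjusted p = 5.64e-10, limma). In all, 4985 genes were higher and 4865 lower of 17336, 50.6% higher, with 53.2% under median-ratio scaling and 45.5% under quantile normalization. Of 52 cytosolic ribosomal proteins 50 rose and 0 fell (50 and 0 adjusted over the list alone; median log2 fold change 2.83; adjusted p = 1.94e-20, and 0.0386 with an estimated correlation). Of 68 ribosome biogenesis genes 65 rose and 0 fell (65 and 1 adjusted over the list alone; median 3.01), among them Mybbp1a and Noc2l by 5.42 and 5.03; adjusted p = 7.65e-23, and adjusted p = 0.0971 with an estimated correlation. Of 45 maternal oocyte factors 38 fell and 1 rose (39 and 1 adjusted over the list alone; median −2.16), with adjusted p = 5.95e-14, and adjusted p = 0.0951 with an estimated correlation.

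Mutant Hdac1 against WT Hdac1 at the late 2-cell stage changed transcripts of both kinds. Gata2, a transcription factor of blood stem cells (chromosome 6, 88193891 to 88207032, plus strand, protein coding), was at 96.3 ± 4.5 FPKM in mutant and 1.27 ± 0.541 in WT embryos, a log2 fold change of 5.44 ± 0.23 (adjusted p = 6.89e-10, limma). Bmp4, a secreted morphogen (chromosome 14, 46383520 to 46390669, minus strand), rose from 0.329 ± 0.107 to 47.9 ± 2.94, and Lgals1, Epop, Prtn3, Lin7b, Atf3 and Adm rose by between 4.88 and 5.05 on the log2 scale. Prtn3, Lin7b and Adm were each listed at 0 in 1 WT library. Fcf1, which acts in maturation of the small ribosomal subunit (chromosome 12, 84970897 to 84983303, plus strand), fell from 73.4 ± 5.70 to 1.87 ± 1.41 FPKM, a log2 fold change of −4.79 ± 0.33 (adjusted p = 2.16e-08). Rpl37a, Bbs2, Pramel7, Gata1, Hsd17b14 and Smyd5 fell, with log2 fold changes from −4.47 to −3.47, and Snhg15 was listed at 0 and at 6.79 FPKM in the mutant libraries against 36.8 and 34.8 in WT. Hdac2 rose from 17.8 ± 2.10 to 45.5 ± 2.50, a log2 fold change of 1.31 ± 0.14 (adjusted p = 1.54e-06). Kdm5b fell from 121 ± 6.67 to 50.2 ± 9.07, a log2 fold change of −1.26 ± 0.25 (adjusted p = 0.000485). Hdac1 itself was higher by 0.76 ± 0.18 (adjusted p = 0.00188).

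In this comparison 5281 genes were higher and 3746 lower of 17336, and 3710 and 2461 of them by at least 2-fold. The median log2 fold change of all genes was 0.169 as deposited, 0.304 with median-ratio scaling and −0.063 with quantile normalization, so single changes near these sizes depend on the scaling. The share of calls that were higher was 58.5% as deposited, 65.2% with median-ratio scaling and 48% with quantile normalization, where 4192 genes were higher and 4540 lower.

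The fixed lists separated by function in the Hdac1 mutant embryos. Of 68 ribosome biogenesis genes 63 fell and 0 rose (64 and 0 adjusted over the list alone; median −1.75), with Nob1 at 7.71 against 69.2 FPKM and Fbl, the rRNA methyltransferase fibrillarin, at 17.8 against 152. Of 52 cytosolic ribosomal proteins 47 fell and 0 rose (50 and 0 adjusted over the list alone; median −1.44), and of 34 translation initiation genes 30 fell and 0 rose (the same counts adjusted over the list alone; median −1.40), with Eif3c at −3.05 ± 0.19. Of 53 splicing genes 37 fell and 0 rose (the same adjusted over the list alone; median −1.04). Of 21 histone acetyltransferases and readers 16 fell and 2 rose (17 and 2 adjusted over the list alone; median −0.816), and of 23 Obox and ZGA activators 18 fell and 2 rose (18 and 3 adjusted over the list alone; median −0.98), among them Dppa2 and Dppa4, upstream regulators of 2-cell genes, at −3.28 ± 0.21 and −2.25 ± 0.12. Of 12 blood markers, the 6 that passed the filter rose (6 adjusted over the list alone; median 3.02), and 6 of the 9 with any value above 0 rose with no filter. They include Cd74 and Hba-a2, the latter listed at 0 in 1 WT library. Gata1, a regulator of red cells, fell. These 7 lists passed camera with both the preset and the estimated correlation, with adjusted p between 5.26e-26 (ribosome biogenesis) and 0.00325 (blood) preset and between 0.0198 and 0.0399 estimated.

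A further 6 lists passed only with the preset correlation. Of 36 proteasome genes 21 fell and 5 rose (adjusted p = 0.123 with an estimated correlation), and of 39 cell cycle genes 19 fell and 6 rose (19 and 7 adjusted over the list alone; adjusted p = 0.0914 with an estimated correlation). Of 38 2-cell burst genes, the family-rich set that peaks at the 2-cell stage, 22 rose and 7 fell (22 and 8 adjusted over the list alone; adjusted p = 0.557 with an estimated correlation). Their members went both ways: Zscan4b rose by 3.26 ± 0.28 and Usp17la by 3.11 ± 0.20, while Pramel7 and Trim43c fell, at −4.06 and −3.30. Of 23 HDAC inhibitor-induced genes 17 rose and 4 fell (18 and 4 adjusted over the list alone; adjusted p = 0.0914 with an estimated correlation), and of 31 neuronal and secretory genes 16 rose and 2 fell (19 and 2 adjusted over the list alone; adjusted p = 0.256 with an estimated correlation). Of 35 members of HDAC1/2 corepressor complexes 17 fell and 7 rose (adjusted p = 0.215 with an estimated correlation), with a median of −0.239 that turned to 0.155 under quantile normalization. Counts of the proteasome and corepressor lists were the same adjusted over the list alone.

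The other 12 mouse lists did not pass in Hdac1 mutant late embryos. Higher and lower members were 17 and 8 of 29 pluripotency and lineage factors, 13 and 4 of 24 imprinted genes, 11 and 4 of 21 integrated stress response genes, 8 and 4 of 16 heat shock genes, and 7 and 1 of 12 cumulus and granulosa markers. They were 13 and 8 of 31 p53 targets (14 and 8 adjusted over the list alone), 6 and 3 of 16 histone deacetylases (4 and 3 of 14 without Hdac1 and Hdac2), 6 and 7 of 18 H3K4 methylation enzymes, 6 and 4 of 14 genes of the DNA methylation machinery, 1 and 1 of 7 sperm markers and 0 and 0 of 13 mitochondrial mRNAs. Except where given, the counts were the same adjusted over the list alone. The medians of the histone deacetylases, 0.252, and of the H3K4 enzymes, −0.345, changed sign under quantile normalization, to −0.089 and 0.047, and that of the mitochondrial mRNAs, −0.026, went to 0.172 under median-ratio scaling. Of 45 maternal oocyte factors 3 rose and 6 fell (1 and 6 adjusted over the list alone), with a median of 0.149 and a mean of 0.006 but a set test directed downward (adjusted p = 0.606).

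Against water-injected late embryos, mutant Hdac1 gave 5090 higher and 4291 lower genes, 54.3% higher. This share was 64.3% with median-ratio scaling, 48% with quantile normalization (4214 and 4557) and 46.1% with a minimum of 5 FPKM. Bmp4 and Gata2 were among the genes that rose, beside Hdac1 itself, at 5.51 ± 0.26 and 5.26 ± 0.23 on the log2 scale. Bmp4 was listed at 0 in 1 water library. Fcf1 and Rpl37a fell, at −4.55 and −5.36, and Rps27 was listed at 0 in both mutant libraries against 57.9 and 37.0 FPKM after water. Hdac2 rose by 0.98 ± 0.14 (adjusted p = 2.70e-05, limma) and Kdm5b fell by 1.40 (adjusted p = 0.000189).

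WT Hdac1 against water at the same stage asked what the injected enzyme does on its own. Hdac1 rose by 4.95 ± 0.18 on the log2 scale and Foxn3, a forkhead factor, from 6.14 ± 4.49 to 18.9 ± 0.494 FPKM. Casp6, an effector caspase, and Mrps23 fell, at −2.17 ± 0.42 and −2.20 ± 0.47. Casp6 was listed at 0 in 1 WT library. Rps27 was listed at 0 and at 13.8 FPKM in the WT libraries against 57.9 and 37.0 after water (adjusted p = 0.0403). Hdac2, at −0.33 ± 0.14 (adjusted p = 0.262), and Kdm5b, at −0.14 ± 0.25 (adjusted p = 0.891, limma), did not pass. There were 61 higher and 318 lower genes, 16.1% higher, with 30.2% higher under median-ratio scaling (87 and 201) and 34% under quantile normalization (49 and 95). A fit of only the groups compared gave 2 and 0 with limma, where all groups gave 2739 genes at an unadjusted p under 0.05. Without Hdac1 WT replicate 1 the lower genes numbered 111, without H2O replicate 1 there were 22 higher and 197 lower, without Hdac1 WT replicate 2 there were 253 higher, and without H2O replicate 2 there were 103. Foxn3 lost its call without any of the libraries except H2O replicate 2, Mrps23 without Hdac1 WT replicate 1 or H2O replicate 2, Casp6 without either replicate 1, and Rps27 without any of the libraries except Hdac1 WT replicate 2. Of the lists, 6 passed with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.463).

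At the early 2-cell stage, mutant Hdac1 against WT Hdac1 changed few genes. Gata2 rose from 0.913 ± 0.0355 to 6.68 ± 0.186 FPKM, a log2 fold change of 2.01 ± 0.23 (adjusted p = 0.000825, limma). Duxf3, a copy of the 2-cell homeobox gene Dux (chromosome 10, 58229979 to 58232675, minus strand), rose from 4.79 ± 0.481 to 20.9 ± 0.646, and its chromosomal neighbour AW822073 from 5.49 ± 0.448 to 23.2 ± 1.76. Akr1c18, a progesterone-metabolising enzyme, fell by −3.29 ± 0.42, Tnc, the matrix protein tenascin C, by −2.25 ± 0.23, and Psap, a lysosomal protein precursor, from 33.4 ± 5.42 to 8.76 ± 1.63. Msx1, Osr2 and Cotl1 also rose, and Timp1, Cd52, Spdye4b, Ddit4l and Guca1a fell. Hdac1 was at −0.74 ± 0.18 (adjusted p = 0.0883), Kdm5b at −0.71 ± 0.25 (adjusted p = 0.408) and Hdac2 at −0.06 ± 0.14 (adjusted p = 1); Hdac1 passed without WT replicate 2 and Kdm5b without mutant replicate 2. Of 38 burst genes 4 fell and 1 rose (23 and 1 adjusted over the list alone; median −0.614), with adjusted p = 1.15e-30, and 0.00924 with an estimated correlation. Of 52 cytosolic ribosomal proteins 7 fell and 0 rose (21 and 0 adjusted over the list alone; median −0.457), with adjusted p = 2.89e-30, and 0.00446 estimated. Of 29 pluripotency and lineage factors 2 rose and 0 fell (4 and 0 adjusted over the list alone), Sox17 and Eomes, with adjusted p = 0.000149, and 0.0496 estimated. Markers of cumulus and granulosa cells were lower in the same mutant libraries (1 of 12 called, 5 adjusted over the list alone; median −0.619; adjusted p = 8.01e-08, and 0.00446 estimated). From the early to the late stage 7 of these 12 markers fell and 1 rose in WT embryos (median −0.94, camera adjusted p = 0.0744). In mutant embryos 1 fell and 6 rose (median 0.532, camera adjusted p = 0.501). Whether such cells were carried into the early WT libraries, and added to the falls named above, was not tested.

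In this early comparison 40 genes were higher and 57 lower, 41.2% higher, and under quantile normalization 62 and 58, 51.7% higher. A pseudocount of 0.1 gave 156 and 144, and a fit of only the groups compared gave 0 and 0 with limma, where all groups gave 1057 genes at an unadjusted p under 0.05. Without Hdac1 WT replicate 1 the counts were 16 and 24, without Hdac1 WT replicate 2 they were 8 and 19, without mutant replicate 1 21 genes were lower, and without mutant replicate 2 21 were higher. Gata2, Duxf3, Akr1c18, Tnc and Psap passed with any of the 4 libraries left out. Msx1, Cotl1, Timp1, Spdye4b, Ddit4l and Guca1a did not pass without WT replicate 1, and AW822073, Msx1, Osr2, Cotl1, Timp1, Cd52 and Ddit4l did not pass without WT replicate 2. Without mutant replicate 1 the calls of Cotl1, Timp1, Cd52 and Ddit4l were lost, and without mutant replicate 2 those of Msx1 and Cd52. The change of the Hdac1 mutant effect between the stages was tested directly. It was higher at the late stage for 3683 genes and lower for 2634, 58.3% higher, with 65.9% under median-ratio scaling and 48.9% under quantile normalization. Among the genes with a higher change were Lgals1 at 6.12 ± 0.36, Slc40a1 at 4.92 ± 1.45 and Nrtn, listed at 0 in 1 WT late library, at 4.70 ± 0.44. Among those with a lower change were Pop1 at −3.75 ± 0.55, Rpl37a at −3.75 ± 0.85 and Fcf1 at −3.64 ± 0.47. In naming these genes, overlap was checked between the late groups only. Of the 40 genes higher in early mutants 36 were also higher in late mutants, where independent lists would share 12.2, and of the 57 lower 33 were also lower, where they would share 12.3.

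Mutant Hdac2 against WT Hdac2 at the late stage gave changes in many of the genes named above. Bmp4 rose from 0.202 ± 0.0264 to 58.8 ± 5.48 FPKM, Atf3, a stress-induced factor, from 0.227 ± 0.052 to 54.0 ± 7.31, and Gata2 by 5.22 ± 0.23 on the log2 scale (adjusted p = 7.70e-10, limma). Oxct2b, Lgals1 and the homeobox genes Pitx3, Bsx and Nkx6-1 rose by between 5.04 and 5.18. Bsx was listed at 0 in 1 WT library. Fcf1 fell from 49.6 ± 7.72 to 0.758 ± 0.282, and Pramel7, Psmb5, Hsd17b14, Smyd5 and Snhg15 fell with log2 fold changes from −4.70 to −3.85. Rps27rt, a near-identical copy of Rps27, also fell and was listed at 0 in 1 mutant library, and Rps27 was listed at 0 in both mutant libraries against 20.5 and 12.0 FPKM in WT. Kdm5b fell from 123 ± 2.91 to 43.5 ± 13.4, by −1.51 ± 0.25 (adjusted p = 9.23e-05), and Hdac2 was higher by 0.55 ± 0.14 (adjusted p = 0.00351), a call lost without WT replicate 2. Hdac1 was lower by 0.51 (adjusted p = 0.0222), which did not pass without either WT library or mutant replicate 2 and turned to 0.049 under quantile normalization.

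There were 5339 higher and 3844 lower genes in Hdac2 mutant embryos, 3849 and 2539 of them by at least 2-fold, with a median of all genes of 0.139 (0.314 with median-ratio scaling and −0.055 with quantile normalization). The share higher was 58.1%, 66.8% with median-ratio scaling (6217 and 3083), 48.2% with quantile normalization (4219 and 4533) and 48.5% with a minimum of 5 FPKM. Of 68 ribosome biogenesis genes 65 fell and 0 rose (66 and 0 adjusted over the list alone; median −1.83; adjusted p = 1.53e-26, and 0.0317 estimated), of 52 ribosomal proteins 48 fell and 0 rose (49 and 0 adjusted over the list alone; 0.0195 estimated), and of 34 translation initiation genes 31 fell and 0 rose (the same adjusted over the list alone; 0.0195 estimated). Of 39 cell cycle genes 23 fell and 6 rose (the same adjusted over the list alone; adjusted p = 0.000186, and 0.0480 estimated), with Plk1 and Ccnb1, a kinase and a cyclin of mitosis, down and Ccnd2, a cyclin of G1, up. Of 24 imprinted genes 17 rose and 3 fell (18 and 4 adjusted over the list alone; adjusted p = 0.0214, and 0.0492 estimated), with Usp29 at −3.20 ± 0.25. Nnat rose, and so did Meg3, by 3.34 ± 0.39, and Peg3, by 2.97 ± 0.23. Proteasome genes (24 of 36 lower, 3 higher; 24 and 4 adjusted over the list alone) had adjusted p = 0.0886 with an estimated correlation. Across the 17336 genes, which are not independent replicates, log2 fold changes of the Hdac1 and Hdac2 comparisons, which share no library, correlated with Pearson r 0.899 and Spearman 0.87. In both, 4296 genes were higher (1626 from independent lists) and 3158 lower (831 from independent lists).

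FK228 against DMSO in mouse late 2-cell embryos tested inhibition of the endogenous enzymes. Vax2, a homeobox factor of the eye (chromosome 6, 83711264 to 83738313, plus strand), rose from 0.345 ± 0.311 to 65.3 ± 3.18 FPKM, a log2 fold change of 5.64 ± 0.27 (adjusted p = 5.71e-10, limma). Adgrb1, Pimreg, Sox8, Foxj1, Oxct2b, Nrtn and Ripk3, a kinase of necroptosis, rose by between 5.10 and 5.51. Pramel7 (chromosome 2, 87489087 to 87497093, minus strand) fell from 112 ± 0.719 to 1.39 ± 0.326, Tbrg1 from 54.4 ± 7.94 to 0.823 ± 0.0492, and Fcf1, listed at 0 in 1 FK228 library, fell by −5.72 ± 0.33. Uqcr10, a subunit of respiratory complex III, Rpl37a, Mocs3 and Timd2 fell, with log2 fold changes from −4.83 to −4.65, and Rps27 was listed at 0 in both FK228 libraries against 24.4 and 25.6 FPKM. Kdm5b fell from 122 ± 23.5 to 29.1 ± 1.89, by −2.01 ± 0.25 (adjusted p = 4.32e-06). Hdac2 rose from 21.1 ± 0.237 to 34.5 ± 1.91 and Hdac1 fell from 91.3 ± 1.06 to 49.4 ± 2.47 (adjusted p = 0.000492), a call lost under quantile normalization.

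In FK228 embryos 5366 genes were higher and 4558 lower, 3772 and 3361 of them by at least 2-fold. The share higher was 54.1%, 65.4% with median-ratio scaling (6949 and 3671), 49.7% with quantile normalization (4762 and 4828) and 45.2% with a minimum of 5 FPKM (3410 and 4134). The median of all genes was 0.147, 0.392 with median-ratio scaling and −0.036 with quantile normalization. Of 68 ribosome biogenesis genes 66 fell and 0 rose (67 and 0 adjusted over the list alone; median −2.46; adjusted p = 1.09e-26, and 0.0312 estimated), of 52 ribosomal proteins 51 fell and 0 rose (the same adjusted over the list alone; median −2.17; 0.0142 estimated), and of 36 proteasome genes 29 fell and 2 rose (the same adjusted over the list alone; median −1.56; 0.0467 estimated). Of 23 Obox and ZGA activators 18 fell and 0 rose (18 and 2 adjusted over the list alone; 0.0261 estimated), with Obox6 at 6.27 against 149 FPKM and Dppa4 at 13.7 against 145. Blood markers (4 of 6 higher, 0 lower, the same adjusted over the list alone) had adjusted p = 0.0900 with an estimated correlation. Imprinted genes did not pass as a list (15 of 24 higher and 6 lower, the same adjusted over the list alone; adjusted p = 0.0628), although Igf2, Nnat, Dlk1 and H19 rose by between 3.49 and 4.72. Fold changes correlated across genes with those of the Hdac1 mutant comparison at r 0.848, with 3985 genes higher in both (1635 from independent lists) and 3288 lower in both (985 from independent lists), and with those of the Hdac2 mutant comparison at r 0.896.

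**Figure D2:**
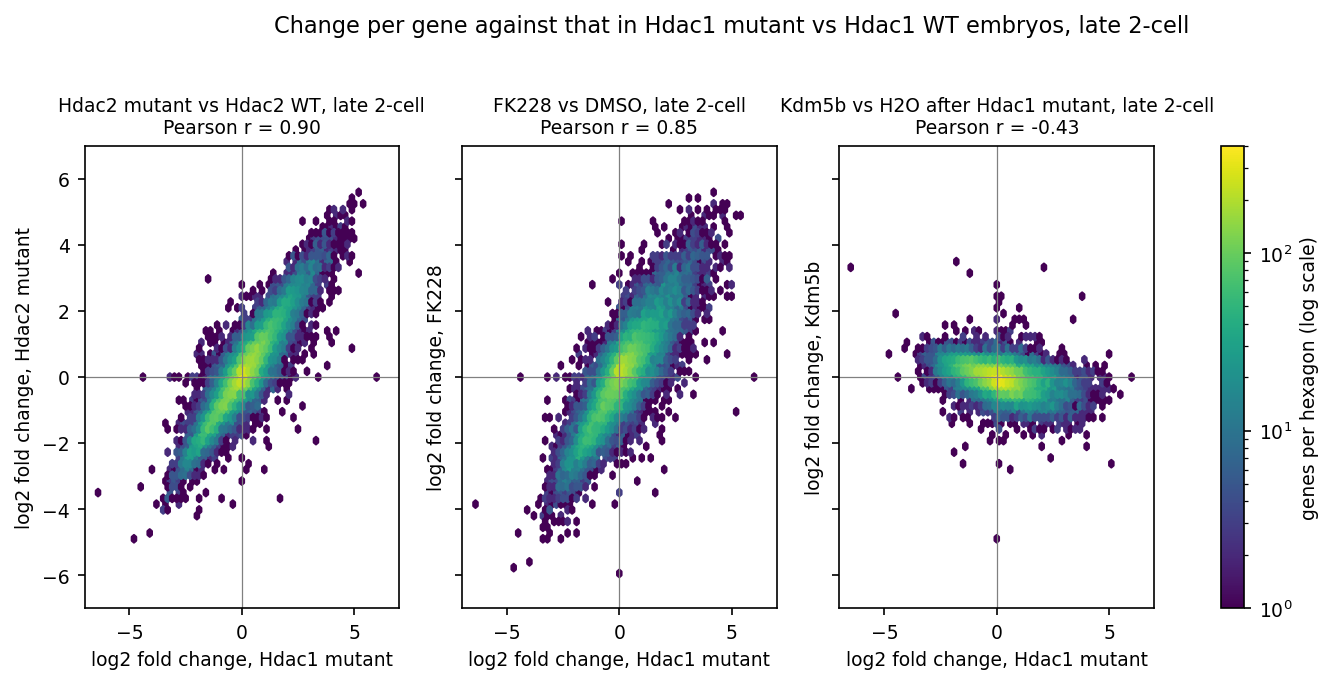
Log2 fold change of each of 17336 mouse genes in Hdac1 mutant late embryos (x axis) against that in the Hdac2 mutant, FK228 and Kdm5b comparisons (y axes), with colour giving genes per hexagon on a log scale. Pearson r across genes was 0.899, 0.848 and −0.429.

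Genes that differ between the stages were followed in the manipulated embryos with lists chosen on libraries outside each comparison. Of 2236 late-rising genes, 1506 fell and 155 rose in Hdac1 mutant embryos (1534 and 165 adjusted over the list alone; median −1.11; adjusted p = 0.00299 with an estimated correlation), 1530 fell and 152 rose in Hdac2 mutant embryos (1576 and 166 adjusted over the list alone; median −1.16; adjusted p = 0.00192) and 1775 fell and 94 rose with FK228 (1800 and 97 adjusted over the list alone; median −1.63; adjusted p = 0.000658). Library medians of these genes in log2(FPKM + 1) were 1.466 to 1.623 in early embryos, 4.585 to 5.032 in late controls and 3.393 to 3.674 in Hdac1 mutant, Hdac2 mutant and FK228 embryos. In embryos with mutant Hdac1 mRNA and a second injection of water they were 4.003 and 4.103, nearer to the controls. Of 894 late-falling genes, 283 rose and 39 fell in Hdac1 mutant embryos (263 and 34 adjusted over the list alone; median 0.33; adjusted p = 0.343 with an estimated correlation). With Hdac2 mutant mRNA 271 rose and 50 fell (244 and 41 adjusted over the list alone; adjusted p = 0.429 with an estimated correlation), and with FK228 395 rose and 29 fell (375 and 28 adjusted over the list alone; adjusted p = 0.0997 with an estimated correlation). The late-falling calls with the preset correlation, adjusted p = 0.00347, 0.0154 and 1.16e-07, were therefore lost with the estimated one.

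**Figure D3:**
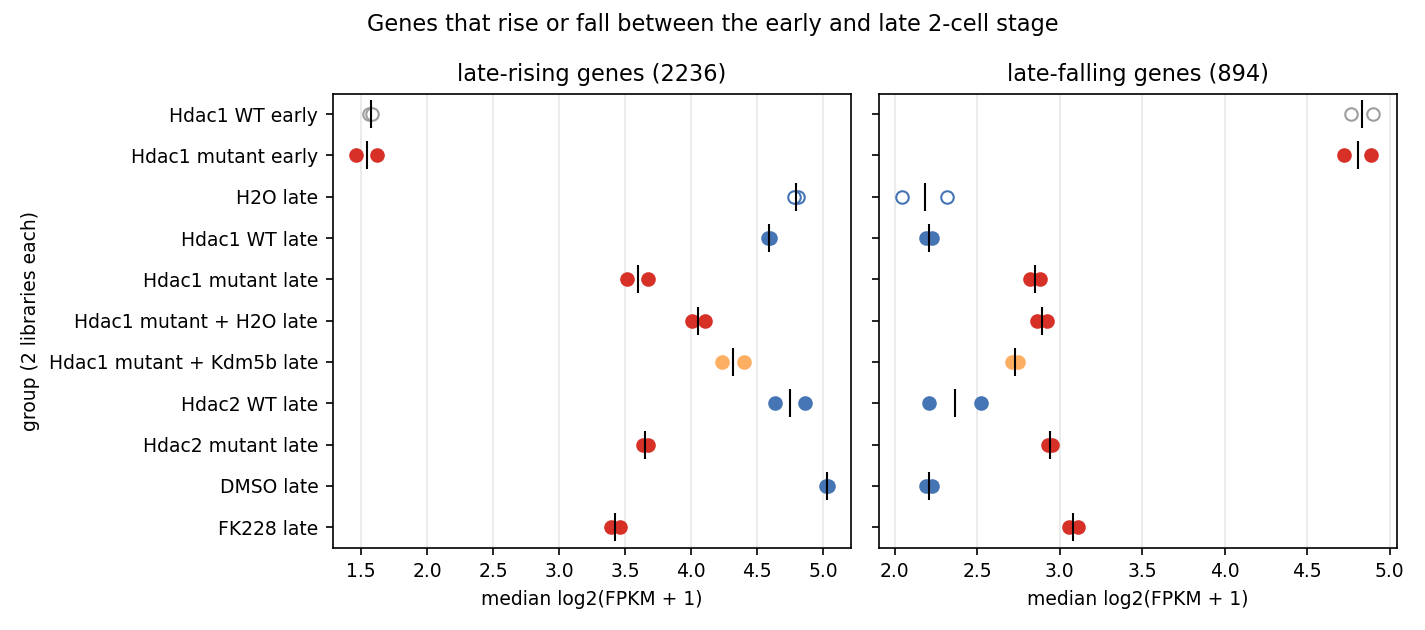
Median log2(FPKM + 1) of late-rising and late-falling genes in each mouse library, with black bars for group means and open circles for the groups on which the lists were chosen. Late-rising medians of the singly injected mutant and FK228 libraries, 3.393 to 3.674, and those of Hdac1 mutant libraries with a second injection of water, 4.003 and 4.103, lay between those of early embryos and late controls.

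Kdm5b mRNA was compared with water in embryos that had received mutant Hdac1 mRNA, to see whether more of the demethylase alters the mutant profile. At 616 FPKM, Kdm5b then stood above the 133 of water-injected and the 121 of Hdac1 WT late embryos, so this was an excess and not a return to the control level. Apart from Kdm5b, which rose by 3.17 ± 0.25 on the log2 scale (adjusted p = 1.39e-05, limma), the genes that rose did so by less: Rpl34 from 23.2 ± 8.92 to 56.4 ± 5.49 FPKM, Eif3c from 17.0 ± 0.328 to 39.4 ± 1.08 and Utp4, a ribosome biogenesis factor, from 6.33 ± 0.837 to 14.8 ± 0.0634. Ints7, Cbfa2t2, Tbrg1 and Nr2c2ap rose by between 1.08 and 1.32. Krt8, an epithelial keratin, fell from 15.9 ± 0.0133 to 5.38 ± 0.00794, and Pmis2, Tmem119, Sectm1b, Prnd, Crnde, Vsir and Stra8 fell, with log2 fold changes from −1.93 to −1.31. Hdac1 was at −0.03 ± 0.18 (adjusted p = 0.972) and Hdac2 at 0.29 ± 0.14 (adjusted p = 0.352). Of 68 ribosome biogenesis genes 5 rose and 0 fell (33 and 0 adjusted over the list alone; median 0.516; adjusted p = 1.10e-24, and 0.0335 estimated). Of 52 ribosomal proteins 3 rose (20 adjusted over the list alone; median 0.474; 0.0257 estimated) and of 34 translation initiation genes 3 rose (17 adjusted over the list alone; 0.0306 estimated), with 0 lower in either. The splicing, corepressor, H3K4 and heat shock lists also passed with the estimated correlation but with few calls: 0 of 53, 2 of 35, 1 of 18 and 0 of 16 rose (3, 3, 1 and 2 adjusted over the list alone). The H3K4 call was the injected Kdm5b. Without Kdm5b the other 17 H3K4 enzymes had a median of 0.268 (adjusted p = 0.000897, and 0.0330 estimated). Burst genes (3 of 38 lower, 6 adjusted over the list alone), all 3 of them Zscan4 copies, had adjusted p = 0.0018 with the preset and adjusted p = 0.408 with an estimated correlation.

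In all, 72 genes were higher and 109 lower after Kdm5b mRNA, 39.8% higher. This share was 17% with median-ratio scaling (24 and 117), 40.7% with quantile normalization (44 and 64), 49.7% with a minimum of 5 FPKM (81 and 82) and 53.5% with length correction (91 and 79). A pseudocount of 0.1 gave 8 and 4, and a fit of only the groups compared gave 1 and 1. These counts rest on every library: without H2O replicate 1 they were 4 and 6, without H2O replicate 2 32 and 97, without Kdm5b replicate 1 2 and 5, and without Kdm5b replicate 2 2 and 8. Of the named genes, only Kdm5b passed with any of the 4 libraries left out. Across genes, fold changes ran against those of the Hdac1 mutant comparison, with which they share no library (Pearson r −0.429, Spearman −0.432). Of the 5281 genes higher in Hdac1 mutant embryos 94 fell (33.2 from independent lists) and 2 rose, and of the 3746 lower ones 64 rose (15.6 from independent lists) and 0 fell. Independent lists ignore expression level, with which both comparisons varied. Of genes under 1 FPKM in water-injected embryos, 49% were higher in Hdac1 mutants and 1.6% fell after Kdm5b mRNA. At 100 FPKM or more, 67% were lower in Hdac1 mutants and 4.5% rose after Kdm5b mRNA. Part of the excess overlap can therefore come from level. The set of genes higher in Hdac1 mutants had a median of −0.199 (adjusted p = 0.0014 with an estimated correlation) and the set of genes lower in them 0.238 (adjusted p = 0.00392). The slope of the Kdm5b on the Hdac1 mutant fold changes was −0.146. Of the late-rising genes 41 rose and 0 fell (85 and 1 adjusted over the list alone; median 0.28; adjusted p = 0.0106 with an estimated correlation), and of the late-falling genes 17 fell and 0 rose (22 and 1 adjusted over the list alone; median −0.129; adjusted p = 0.267 with an estimated correlation).

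In bovine 8/16-cell embryos, FK228 against DMSO asked the same question at the stage when the bovine genome is activated. H2B, a core histone, rose by 5.20 ± 0.24 on the log2 scale (adjusted p = 1.85e-05, limma) and was listed at 0 in 1 DMSO library. SLC6A19, an amino acid transporter, rose from 0.391 ± 0.251 to 44.5 ± 6.53 FPKM, and ENGASE from 0.650 ± 0.222 to 43.1 ± 3.60. NRGN, SNN, ARC, an activity-regulated neuronal gene, and PYGM, muscle glycogen phosphorylase, rose by between 3.89 and 4.39. PRDM14 fell from 67.6 ± 21.1 to 1.11 ± 0.381 and ESRRB from 55.2 ± 11.4 to 2.03 ± 0.844, both pluripotency regulators. URGCP fell from 70.3 ± 27.2 to 0.266 ± 0.142, TKT, the transketolase of the pentose phosphate pathway, from 422 ± 36.9 to 16.7 ± 5.94, and SLC34A2, MTHFD1L and XCL1 fell with log2 fold changes from −4.76 to −4.32. XCL1 was listed at 0 in 1 FK228 library. BAP1, a histone H2A deubiquitinase, was listed at 0 in both FK228 libraries against 20.9 and 26.9 FPKM. HDAC2 fell by 0.98 (adjusted p = 0.00208), whereas HDAC1 was at −0.41 ± 0.16 (adjusted p = 0.0628) and KDM5B at −0.36 ± 0.19 (adjusted p = 0.138); without FK228 replicate 1 KDM5B passed, at −0.56.

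There were 2789 higher and 3451 lower bovine genes of 12590, with 1839 higher without DMSO replicate 1 and 1729 without FK228 replicate 2. Of 53 ribosomal proteins 43 fell and 2 rose (44 and 2 adjusted over the list alone; median −0.962), of 68 ribosome biogenesis genes 51 fell and 2 rose (53 and 2 adjusted over the list alone), of 53 splicing genes 33 fell and 1 rose (34 and 1 adjusted over the list alone), of 33 translation initiation genes 26 fell and 0 rose (27 and 0 adjusted over the list alone) and of 36 proteasome genes 25 fell and 0 rose (26 and 1 adjusted over the list alone). Of 28 pluripotency and lineage factors 15 fell and 4 rose (15 and 5 adjusted over the list alone), and of 21 eutherian embryonic genome activation genes 11 fell and 2 rose (12 and 3 adjusted over the list alone), with DPPA4 and DPPA2 at −3.13 and −2.92 and ZSCAN5B at 2.24. Of 34 maternal oocyte factors 10 rose and 0 fell (6 and 0 adjusted over the list alone). These and the cell cycle and H3K4 lists, 10 in all, passed with the preset correlation (adjusted p from 3.12e-10 to 0.0155) and 0 passed with an estimated one, where the lowest adjusted p was 0.515; this fit had 2 residual degrees of freedom. By equal symbols, fold changes of 9850 genes correlated across species at r 0.363 for FK228 in mouse. Of these, 1020 were higher in both (605 from independent lists), 1534 lower in both (967 from independent lists), 500 higher in mouse and lower in cattle, and 344 the reverse.

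**Figure D4:**
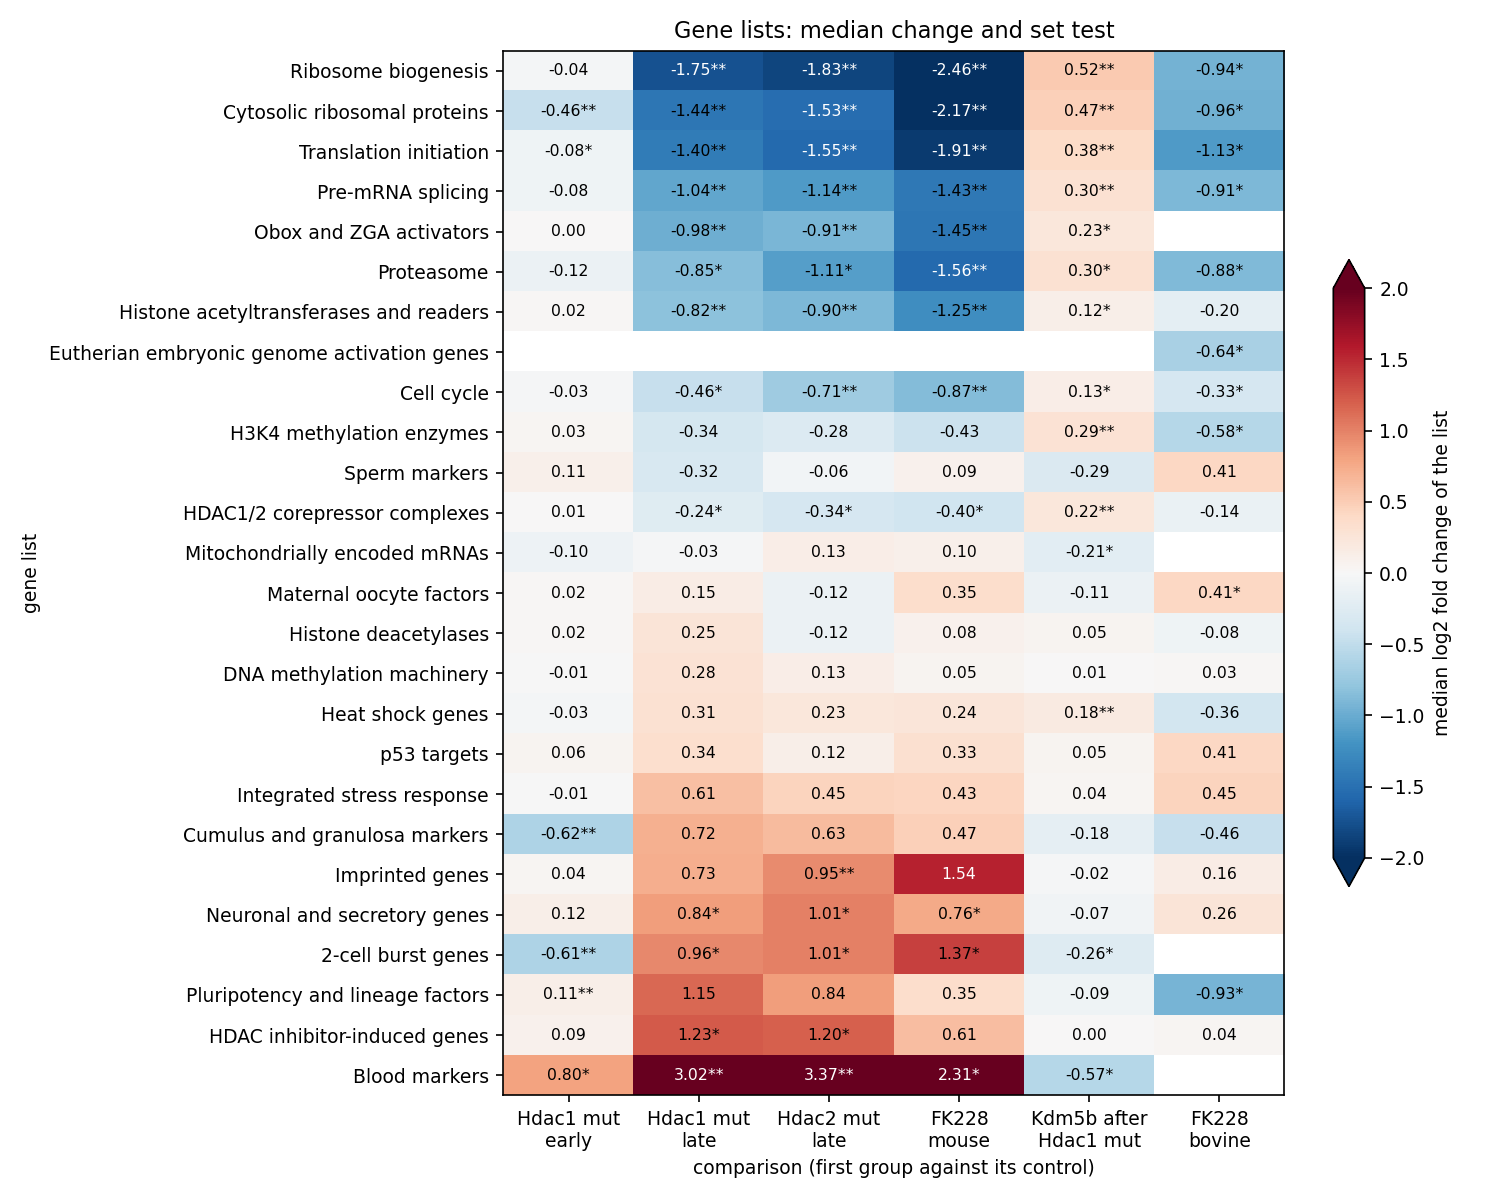
Median log2 fold change of each gene list (rows) in 6 comparisons (columns), with 1 asterisk for an adjusted p under 0.05 with the preset correlation and 2 for one that also passed with an estimated correlation; blank cells were not tested and the colour scale ends at 2 either way. Of the lists that passed, the corepressor medians of the Hdac1 and Hdac2 mutant late columns change sign under quantile normalization.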

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

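The tests of a whole-embryo delay and of scaling were chosen after the result was seen; that of gene length was added after the data were seen, but its limits were written before its own result was.

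The effect of mutant Hdac1 differed between the stages: the test of the difference itself passed for 3683 genes whose log2 fold change was higher at the late stage and 2634 whose change was lower. The balance depends on the processing: 58.3% were higher as deposited, 65.9% with median-ratio scaling (4389 and 2275), 48.9% with quantile normalization (2915 and 3042) and 47.6% with length correction (2969 and 3264). At the late stage itself, transcripts that normally rise were lower, by medians of −1.11, −1.16 and −1.63 in Hdac1 mutant, Hdac2 mutant and FK228 embryos. If whole embryos were late in development, transcripts that normally fall would be retained to the same degree. As deposited, the missing share of the fall was at most 0.362 of the missing share of the rise. That ratio was not computed with other scalings. With median-ratio scaling the late-rising medians shrank to −0.943, −0.915 and −1.288, so the ratio may depend on the scaling. Of the 5281 genes higher in Hdac1 mutants than in WT late embryos, 3834 were also above WT early embryos. Genes that peak between the stages could do so in delayed embryos, so this count does not decide. Of 38 burst genes 36 rose and 2 fell from early to late in mutants, against 16 and 12 in WT. A delay is therefore not excluded. Removing the trend with gene length left the late-rising medians at 1.0501 times their size or more. The correction also lowered the median of all genes. It went from 0.169 to −0.009 in Hdac1 mutant, 0.139 to −0.036 in Hdac2 mutant and 0.147 to 0.07 in FK228 embryos. Ratios above 1 can come from that shift, so they show only that the fall was kept. With quantile normalization late-rising genes stayed at −0.977 or lower relative to all genes. A candidate explanation is that deacetylase activity may be needed for genes that are switched on late; this is a hypothesis from the same data, and mixtures of arrested and dividing embryos were not tested.

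The effects of mutant Hdac1 and mutant Hdac2 differed for 7 genes higher and 11 lower in the direct test with limma, with 1658 at an unadjusted p under 0.05, and for 0 and 0 in a fit of only the groups compared. Without Hdac1 mutant replicate 1 the counts were 11 and 7, without Hdac1 mutant replicate 2 48 and 35, without Hdac1 WT replicate 1 13 and 24, and without Hdac1 WT replicate 2 18 and 33. Without Hdac2 mutant replicate 1 there were 4 lower, without Hdac2 mutant replicate 2 or Hdac2 WT replicate 1 there were 6 lower, and without Hdac2 WT replicate 2 there were 14 and 6.

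The effects of mutant Hdac1 and FK228 differed for 826 genes that were higher and 382 that were lower with the mutant, 68.4% higher, but 52% higher with median-ratio scaling (483 and 445) and 52.9% with quantile normalization (586 and 522). A fit of only the groups compared, with few residual degrees of freedom, called 23 and 4. By the rule for naming genes, Dmrta2 and Irx5 came first among the former at 3.33 ± 0.39 and 3.19 ± 0.40. Foxj1, at −3.05 ± 0.49, and Adgrb1 came first among the latter. Adgrb1 was listed at 0 in both Hdac1 WT late libraries, which can be a failed estimate, so no size is given for it. Without FK228 replicate 1 there were 237 lower, without FK228 replicate 2 307 and 153, without DMSO replicate 1 309 and 120, and without DMSO replicate 2 334 and 150.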

How the results depend on the processing

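The length correction and lists without the injected genes were chosen after the data were seen; all other settings were planned. Of 2191 recomputed values of named genes 207 lost a call, 7 gained one and 1 reversed, and of 1006 recomputed list results 108 lost a call, 13 gained one and 2 reversed. The counts of calls in the Hdac1 mutant, Hdac2 mutant and FK228 late comparisons moved by less than 1.5 times under every setting, except the higher genes below. Unless said otherwise the cause was not tested. Absolute depth is unknown, so the limit it sets on low genes cannot be given.

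With a minimum of 5 FPKM, which tests fewer genes, higher genes numbered 3377 for Hdac1 mutant against water, 3383 for the Hdac2 mutant and 3410 for FK228 in mouse, and the Hdac1 against FK228 and Hdac1 against Hdac2 differences had 254 and 6 lower. With no filter, higher genes were 62 in the early comparison, and 12 were higher and 19 lower in the Hdac1 against Hdac2 difference. A pseudocount of 0.1 gave 109 higher for WT Hdac1 against water, 156 higher and 144 lower in the early comparison, 8 and 4 for Kdm5b, 2 lower for Hdac1 against Hdac2 and 122 lower for Hdac1 against FK228.

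Median-ratio scaling gave 201 lower for WT Hdac1 against water, 24 higher for Kdm5b and 483 higher for Hdac1 against FK228. Quantile normalization gave 95 lower for WT against water, 62 higher in the early comparison, and 44 higher and 64 lower for Kdm5b. Late against early Hdac1 mutant embryos, with 7038 higher and 4475 lower (61.1% higher), went to 5105 and 5615 (47.6%). The medians of all genes there, 0.372, and for the Hdac1 mutant against water, 0.096, went to 0.538 and 0.287 with median-ratio scaling and −0.022 and −0.074 with quantile normalization. Length correction gave 150 lower for WT against water, and no variance trend gave 41 higher for Kdm5b. Hdac1 in Hdac2 mutant embryos reversed to 0.049 with quantile normalization. With limma's camera, so did the list HDAC1/2 corepressor complexes, Hdac1 mutant vs Hdac1 WT, late 2-cell (adjusted p = 0.967), and the mitochondrial list after Kdm5b (adjusted p = 0.939).

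Fitting only the groups compared leaves few residual degrees of freedom, and limma then called 3439 higher for the Hdac1 mutant, 2 and 0 for WT against water, 0 and 0 in the early comparison, 1 and 1 for Kdm5b, 0 and 0 for Hdac1 against Hdac2, and 23 and 4 for Hdac1 against FK228. With all groups, an unadjusted p was under 0.05 for 2739 genes in WT against water, 1057 in the early comparison and 1658 for Hdac1 against Hdac2. The replicate number as a block moved 1 count by over 1.5 times, to 94 higher for WT against water. The numbers were not shown to pair the libraries: deviations of same-numbered libraries correlated at −0.008 to 0.175 in mouse and 0.233 in cattle, over 2 pairs.

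With an estimated correlation, lists called went from 13 to 7 for the Hdac1 mutant, 14 to 6 against water, 6 to 0 for WT against water (2 with median-ratio and 1 with quantile scaling), 8 to 1 and 12 to 0 for stage in WT and mutant embryos, 14 to 9 for the Hdac2 mutant, 14 to 7 for Kdm5b and 10 to 0 in cattle. The late-falling list held 894 genes at the main threshold but only 19 at a list threshold of 4, where a set test has less power. Late-falling genes had, with limma's camera at an estimated correlation, adjusted p = 0.343, 0.429, 0.0997 and 0.267 for Hdac1, Hdac2, FK228 and Kdm5b, and at a list threshold of 4 with the preset correlation, adjusted p = 0.340, 0.975 and 0.244 for Hdac1, Hdac2 and Kdm5b. By the same limma test the genes lower in Hdac1 mutants had adjusted p = 0.149 in early embryos, and the genes higher and lower in them 0.251 and 0.178 in cattle.

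Leaving out libraries moved these counts to 22 to 253 higher and 111 to 468 lower for WT against water, 8 to 37 and 19 to 76 in the early comparison, 2 to 32 and 5 to 97 for Kdm5b, 5 to 48 and 4 to 35 for Hdac1 against Hdac2, 307 to 826 and 120 to 544 for Hdac1 against FK228, and 1729 to 2486 higher in cattle.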

Other observations

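The tests of sequencing depth, blood cells, Hdac1 mRNA, a single library, scaling after Kdm5b mRNA and the spread between libraries, and those of gene families, were chosen after the result was seen; that of genomic DNA was not.

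How far a gene moved went with its level in water-injected late embryos. In Hdac1 mutant embryos the median log2 fold change was 0.213 over 6192 genes at 1 to 10 FPKM, −0.497 over 4903 at 10 to 100 and −0.977 over 594 at 100 or more. With FK228 in mouse the values were 0.157, −0.793 and −1.314, and after Kdm5b mRNA they ran the other way, −0.034, 0.155 and 0.269. The overlaps given above for independent lists do not allow for this dependence on level. Genes under 1 FPKM in those embryos are left out, since the filter keeps them for being higher in other libraries. Genes of the X chromosome (709 tested) had medians of 0.313, 0.436 and 0.282 in Hdac1 mutant, Hdac2 mutant and FK228 embryos, against 0.165, 0.126 and 0.143 for 16316 autosomal genes; these differences were not tested. Among stress genes, Ddit3 and Xbp1 rose in Hdac1 mutant embryos by 2.20 ± 0.31 and 2.96 ± 0.45, and the p53 targets Btg2 and Bbc3 by 3.10 ± 0.22 and 2.89 ± 0.35, although neither list passed. Hdac11 and Hdac7, each listed at 0 in 1 WT library, and Hdac3 rose and Sirt1 fell, from 115 to 20.2 FPKM.

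Some genes of other tissues were higher in Hdac1 mutant, Hdac2 mutant and FK228 late embryos: blood markers and neuronal and secretory genes passed as lists with the preset correlation. Only 6 of 12 blood markers and 31 of 43 neuronal and secretory genes were tested, against all other genes. Of all genes tested that were under 1 FPKM in water-injected embryos, 49%, 53.4% and 53% were called higher in these groups. The passes therefore do not set these lists apart from other silent genes. With an estimated correlation blood markers did not pass with FK228 and neuronal and secretory genes passed in none of the 3, cumulus markers did not pass with either, and 1 of 7 sperm markers rose and 1 fell in each. On average 13908 genes reached 1 FPKM in Hdac1 mutants against 11456 in WT. Depth of these groups was at most 1.003 times that of their controls, which argues against deeper sequencing. Genomic DNA would raise all silent genes. The mean FPKM of 406 receptor genes did rise, from 0.024675 to 0.058697 in Hdac1 mutant embryos. It rose from 0.022084 to 0.060019 in Hdac2 mutant embryos and from 0.016597 to 0.088675 with FK228. This rise was at most 0.0759 of that of 4784 other silent genes. The ratio argues against genomic DNA as the source of most of the mean rise, but a low background from it is not excluded. Hba genes were at 38.1, 53.7 and 71.6 FPKM on average in the 3 groups, and Hbb genes at 0.002 of that level with FK228, but Hbb genes were listed at 0 in every library of the 2 mutant groups and in FK228 replicate 1. Such a 0 can be a failed estimate, so blood cells stay open as a source of the blood markers. A loss of repression of silent genes when deacetylases fail may also be involved; this was not tested.

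After Kdm5b mRNA, genes moved against the Hdac1 mutant effect by a small amount. The score of genes lower minus genes higher in Hdac1 mutants differed by 0.461, 5.95 standard errors of the spread within 9 groups, where the Hdac1 mutant effect itself was −2.895. With 1 of the 4 libraries left out the difference was still at least 0.351 (without H2O replicate 1), 3.70 standard errors, which argues against a single library as the whole cause. The share of the genes lower in Hdac1 mutants that lay above 0, at least 72.5% with a library left out, says less: between replicates of a group it reached 71.8%, above the limit of 65% first set for it. With quantile normalization the score differed by 0.421, 6.44 standard errors, which argues against scaling as the cause. Less mutant Hdac1 mRNA stays open. The estimated fall of Hdac1 was 2.1%, but the 95% interval of its log2 fold change reached down to −0.404, a fall of 24.4%. The part reversed was 15.9% of the effect in singly injected mutant embryos and 18.5% of the difference between mutant embryos with the second injection of water and water-injected embryos, groups unlike in injections and Hdac1 level. Setting these shares against the fall assumes an effect in proportion to Hdac1 mRNA, which was not shown. Scores were 0.231 and 0.472 in singly injected mutants, with Hdac1 at 4782 FPKM. They were 0.528 and 0.749 in mutants with the second injection of water, with Hdac1 at 861 FPKM. Since these groups also differ in injections, their scores do not decide. Kdm5b stood above its control level, so the values do not show that the mutant profile depends on the fall of Kdm5b, and an effect of a second injected mRNA as such was not tested, since no control mRNA group was analysed here.

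Homeobox, forkhead, Sox, T-box, Gata, Wnt, Bmp and Fgf genes were common among the genes higher in mouse: 193 of 242 rose and 9 fell in Hdac1 mutants, 196 and 10 in Hdac2 mutants and 200 and 10 with FK228, while after Kdm5b mRNA 0 rose and 4 fell. The filter favours silent genes that are high in these groups, but with no filter 210, 214 and 212 of 289 rose, 72.7% to 74% against 19.7% to 21.5% of other genes. Of the 59 members at 1 FPKM or more in water-injected embryos 30, 28 and 33 rose, 47.5% to 55.9% against 19.8% to 21.3% of other genes. In cattle, 78 of 186 rose and 32 fell with FK228, 41.9% against 21.9% of other genes, a ratio of 1.919 (camera p = 0.000108, and 0.257 with an estimated correlation). Counts with no filter and of expressed members were made for mouse only, so the bovine share may still lean higher through the filter. The family definition was narrowed after a first result of 86 of 202, a ratio of 1.951. With FK228, 14 of 29 pluripotency and lineage factors were higher and 8 lower in mouse, where the list did not pass, against 4 of 28 higher and 15 lower in cattle, where it passed with the preset correlation but not with an estimated one (adjusted p = 0.515). A shared response of developmental regulators was not shown, nor was an opposite one.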
